A study of Homo sapiens with 4 samples.

How the data were processed

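H3K27ac was measured by chromatin immunoprecipitation and sequencing in KGN cells, in 1 IP and 1 input library per condition (control, and testosterone at 10 um for 24 h), 4 libraries in all. The authors deposited 1 table of called regions per condition, each made from 1 IP against its own input. The submitters' processing notes name Bowtie2 2.0, MACS2, ChIPseeker and bedtools, and the genome builds hg38 and mm10, and the settings of the caller are not given in the sources used here. Pileup, a column of both tables, was read as the signal in fragments at the summit. That the caller had scaled the larger library of each pair to the smaller was inferred from the values. Fold enrichment in the deposited tables is a ratio, the pileup plus 1 over the local background plus 1. Significance is deposited as -log10 p and -log10 q. In the testosterone table both significance columns had lost their headers to a spreadsheet error, and 1 gene symbol had been turned into a date, so the columns were identified from their order and values, and the symbol was recovered from its Ensembl identifier.

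These units were checked on the values. A local background solved from fold and pileup gave back the -log10 p of every region as a Poisson upper tail, with a largest difference of 0.00385 in the control and 5.47e-05 in the testosterone table. Region names ran without gaps to 19110 and 604, and no regions of a table overlapped. The lowest -log10 q was 1.32 in the control and 1.31 in the testosterone table. Annotated genes lay on the same chromosome and overlapped their RefSeq position on GRCh38.p14 for 99.97% of control and 100% of testosterone regions with a matched symbol, so positions were read as GRCh38. Of the symbols, 9665 of 9767 and 483 of 488 matched RefSeq directly or by synonym.

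Depth was compared through the caller's own values, since library totals were not used here. The lowest background was taken as the smaller library times the fragment length over the genome size, and the shortest region (231 bp in control, 223 bp with testosterone) as the fragment length. Testosterone pileups were whole numbers within 0.006. Of the testosterone backgrounds above the lowest, 23.4% were multiples of 0.5818, where 0.688% would be by chance, and this step was read as the factor applied to the input. The other backgrounds do not lie on a step, so the input depth rests on this part of them. These readings gave an IP depth of 1.07 times the input in control cells and 0.582 times with testosterone. They rest on the usual arithmetic of the caller and carry no error of their own.

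Chromosomes 1 to 22 and X were used, and overlapping entries of a list were to be merged, which joined none. Regions were called shared at an overlap of at least 1 bp, and the overlap was set beside 100 seeded shuffles of the testosterone regions on their own chromosomes. Promoter regions were those within 1 kb of the gene start that the authors' annotation gives as nearest, for protein-coding genes. The plan had assumed a separate annotation of gene starts. The RefSeq table used carries no strand, so each region was credited to the authors' nearest gene only, and a neighbor sharing a bidirectional promoter was missed. A region within 1 kb of a non-coding gene was classed with those up to 3 kb from a start. Summit positions used the gene starts and strands of the authors' annotation. No test between the conditions was made, since each had 1 IP library. Shares have Wilson 95% intervals, and the interval of a ROC area is that of Hanley and McNeil.

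For 12 gene lists, the number of control-marked genes also marked after testosterone was set beside 10000 random lists of control-marked genes, matched on the tenth of control fold of their strongest promoter region. Genes were named by a rule: 13 genes always given, from each list the 2 highest by control fold of those marked in control only and of those marked in both, any marked after testosterone only, and the 10 promoters and 3 other regions of largest fold that were control only, in both and testosterone only. Some genes that this rule takes are not reported here. Groups, tests, lists, the naming rule and most alternatives were set before the data were examined. The alternatives were a stricter -log10 q (5 and 10) or fold (4), overlaps of 50%, sharing within 1 kb, other merging (none, or within 500 bp), every sequence name, promoter windows of 500 bp and 3 kb, starts of every annotated gene, a control list reduced to its strongest regions, strength by -log10 p or pileup, and unmatched random lists. Another 7 were added after the data were seen: the control list at the weakest testosterone -log10 p, control regions matched on -log10 p, sharing within 10 kb, whole gene bodies, random lists matched on region width or on pileup, and strength within 10 groups of like region width. The code was tested on simulated data: all 200 regions planted on control regions were found, and 6 of 200 random lists passed at 2.5%. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.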

Results

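Acetylation of histone H3 at lysine 27 (H3K27ac), a mark of active promoters and enhancers, was mapped by chromatin immunoprecipitation and sequencing in KGN cells, an established human granulosa tumor cell line. Granulosa cells surround the oocyte and make estrogen and progesterone. One immunoprecipitated (IP) library and 1 input library came from control cells. A further IP library and its input came from cells given testosterone, written as 10 um in the labels, for 24 h. The title given to the series concerns loss of this mark after testosterone. The authors called regions once per condition, on 1 IP against its own input, so no difference between the conditions has a replicate check and no p-value between them is given. Total reads per library were not analysed here. Backgrounds in the lists place the depth of the testosterone IP at 1.03 times that of the control IP, and the depth of its input at 1.89 times that of the control input. Intervals are Wilson 95% intervals and cover counting error only. Fold enrichment and pileup are the authors' values, scaled by the caller to each list's own libraries. Where they are given for both lists they describe each list and do not measure a difference between them. Positions are on GRCh38.

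The first comparison asked how many regions carried the mark in each condition. H3K27ac regions numbered 19110 in control cells and 604 in testosterone-treated cells, a ratio of 31.6. Control regions covered 10.3 Mb of the genome and testosterone regions covered 186 kb. At the promoters of CCT5, a subunit of a cytosolic chaperonin, of TXN2, the mitochondrial thioredoxin, and of the kinase gene ABL1, control cells had some of their strongest regions and testosterone-treated cells had none. Regions were found on 23 chromosomes in control cells and on 22 after testosterone. The chromosome without a testosterone region was 13, where control cells had 130 regions. In proportion to the control list, 4.11 regions would have fallen there. By the same measure chromosome 19 had 26 testosterone regions against 51.1, chromosome 1 had 89 against 64.2 and chromosome 10 had 43 against 26.4.

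Control regions had a median width of 411 bp and testosterone regions one of 283 bp. The median fold enrichment over the local background was 4.99 within the control list (interquartile range 4.08 to 6.31) and 4.64 within the testosterone list (4.29 to 5.10). The control list reached a pileup of 110.5 fragments at the summit, after the scaling by the caller, and the testosterone list one of 35. The ratio was 27.2 at a fold of at least 4 in both lists, 45.7 at 5 and 119 at 6, and at 8 or more 1965 control regions and no testosterone region remained. It also grew with a stricter -log10 p or -log10 q. At a -log10 p of at least 8, 10441 control and 135 testosterone regions remained, a ratio of 77.3. An equal -log10 q is not an equal -log10 p, since the lowest -log10 p was 3.71 in the control and 4.92 in the testosterone list. At a -log10 q of at least 5, 10354 control and 10 testosterone regions remained, a ratio of 1035. At 10 or more, 3775 and 1 remained. That 1 region (chromosome 21, 6370269 to 6370511, between genes, nearest coding gene CBSL, a near copy of CBS) was chosen after its values were seen. It had the pileup of 35 given above, at a fold of 6.49.

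**Figure D1:**
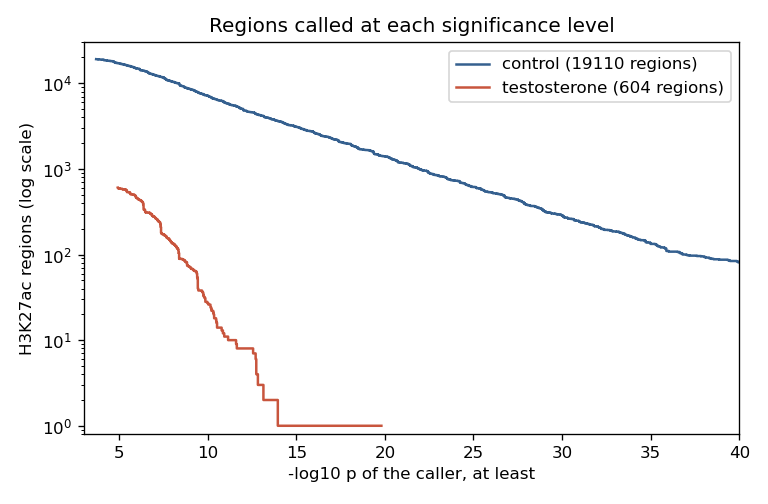
Number of H3K27ac regions (vertical axis, log scale) with at least the -log10 p on the horizontal axis, for the control list and the testosterone list (1 IP library each). At the weakest testosterone -log10 p of 4.92 the lists held 17174 and 604 regions, and at 10 they held 7148 and 27.

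The next comparison asked whether the regions found after testosterone were those of control cells. Among the 604 testosterone regions, 170 overlapped a control region by at least 1 bp (28.1%, 24.7 to 31.9). Regions of the same widths placed at random on the same chromosomes overlapped control regions in at most 1.66% of cases over 100 shuffles. Seen from the control list, 169 of 19110 regions overlapped a testosterone region (0.884%, 0.761 to 1.03). The strongest shared promoter regions of the control list lay at THAP9, a gene derived from a DNA transposase (fold 18.6), MEIG1 (18.1), and STT3B, a catalytic subunit of the oligosaccharyltransferase (17.5). SLC35C1, the Golgi GDP-fucose transporter, followed at 15.01, with CYP4V2 (13.6), the mannosyltransferase gene ALG9 (12.7), NBPF1 (11.8), CD160 (11.4), PPP2R5B (10.7) and SH2B1 (10.6) after it. The control region at STT3B (chromosome 3, 31531846 to 31533968) was 2123 bp wide, and the testosterone region inside it spanned 242 bp. At THAP9 the widths were 339 and 276 bp. NBPF1 belongs to a family of near-identical copies, among which reads are hard to place. Shared regions outside promoters with the largest control fold were assigned to NTMT1 (13.8), ZSCAN16 (11.9) and ZFHX3 (10.5).

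The other 434 testosterone regions did not overlap a control region, and 302 of them (69.6%) lay within 10 kb of one, where at most 14.98% of shuffled regions did. Their median gap to the nearest control region was 2.65 kb. At promoters, those with the largest testosterone fold were at ZNF143, a transcription factor gene (7.396), EFNA3, an ephrin gene (6.19), NFIA, a nuclear factor I gene (6.17), SARNP (6.14), TCHP (6.03), CHMP4A (6.03), ADI1 (6.03), KLHL23 (6.03), CNPY4 (6.03) and PPP1R3E (5.99). Control cells had a promoter region of their own at each of these genes except ADI1 and CNPY4. At ZNF143 the testosterone region (chromosome 11, 9459661 to 9460134) lay 4 bp from a control region, and at NFIA the gap was 201 bp. Outside promoters, the largest folds among these regions were near ADGRE5 (6.96), ZFP64 (6.93) and SIGIRR (6.50). The share of testosterone regions found in control cells moved with the rule for sharing, from 8.11% for a reciprocal overlap of 50% to 78.1% when regions within 10 kb counted. It was 2.81% when the control list was reduced to its 604 strongest regions, and 50% when both lists were limited to a -log10 q of at least 5, which left 10 testosterone and 10354 control regions.

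A further comparison concerned position relative to genes. Promoter regions, within 1 kb of the start of a protein-coding gene, made up 10825 of the control regions (56.6%, 55.9 to 57.3) and 189 of the testosterone regions (31.3%, 27.7 to 35.1). Introns held 13.1% of control and 25.3% of testosterone regions, and 17.1% and 26.7% lay outside genes. Testosterone regions that overlapped a control region were at promoters in 57.6% of cases (50.1 to 64.8), and the others in 20.97% (17.4 to 25.04). Control regions matched one to one to the testosterone list on -log10 p, an alternative chosen after seeing the data, were at promoters in 42.5% of cases (38.7 to 46.5). With a -log10 q of at least 5 the testosterone share was 60%, over 10 regions, and the control share 69.2%, and at 10 or more the single region was not at a promoter.

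**Figure D2:**
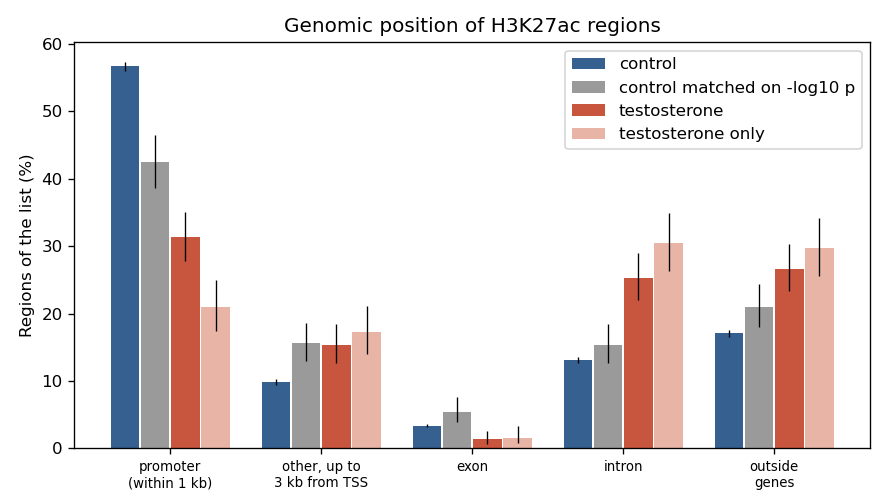
Share of regions (vertical axis, percent) in each class of position (horizontal axis) for the control list, control regions matched to the testosterone list on -log10 p, the testosterone list and its regions that overlap no control region. Bars start at 0, lines are Wilson 95% intervals, and the promoter share falls from 56.6% in the control list to 42.5%, 31.3% and 20.97% in the others.

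Summits also lay differently around gene starts. Of the control regions with a summit within 3 kb of a start, 51.4% (50.5 to 52.2) had it within 300 bp, against 29.7% (24.7 to 35.4) of the testosterone regions. The median distance was 287 bp and 609 bp. In control regions matched on -log10 p these values were 42.9% (37.8 to 48.2) and 408 bp. The control region at EP300 (1507 bp wide) overlapped the gene start, and the nearest edge of that at FOXL2 (1701 bp) lay 6 bp from it. These distances are of the region and do not place its summit.

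**Figure D3:**
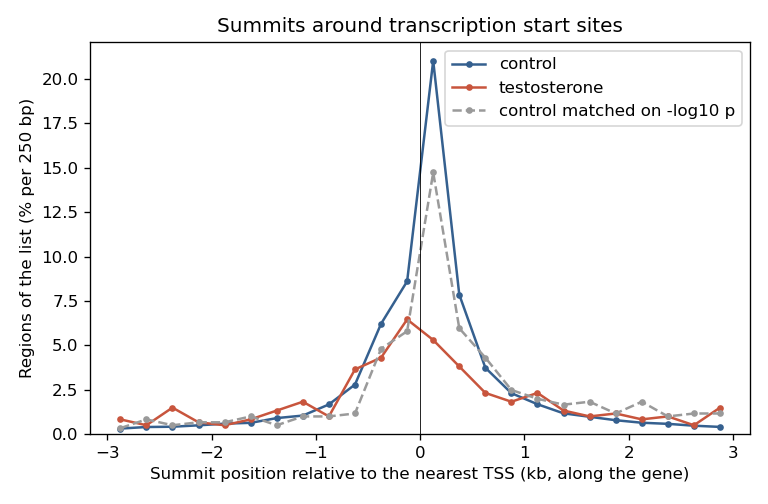
Share of each list's regions (vertical axis, percent per 250 bp) by the position of the summit relative to the nearest gene start (horizontal axis, kb along the gene) for the control list, the testosterone list and control regions matched on -log10 p. The control lists peak just downstream of the start, and 29.7% of the testosterone summits within 3 kb lie within 300 bp of it, against 51.4% in control.

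Counted by gene, 8187 of 19974 protein-coding genes (41.0%) had a promoter region in control cells and 186 (0.931%) after testosterone. Both lists marked 157 genes, which is 1.92% (1.64 to 2.24) of the control genes and 84.4% (78.5 to 88.9) of the testosterone genes. A gene marked in both lists need not have overlapping regions: 98 testosterone promoter regions overlapped a control region and 91 did not. FOXL2, the transcription factor that maintains granulosa cell identity, had a control promoter region (chromosome 3, 138945432 to 138947132, fold 10.7) and none after testosterone. The same held for FKBP5, a textbook androgen- and glucocorticoid-responsive gene (fold 8.52), for the acetyltransferase gene EP300 (11.3) and for the deacetylase gene HDAC1 (2.505). The HDAC1 region was weak, in the tenth of control regions with the lowest fold and at a -log10 q of 1.93. Its absence after testosterone therefore says little. Neither list held a region assigned to, or lying on, FSHR, CYP19A1, STAR, HSD3B2 or AMH, the genes of the follicle-stimulating hormone receptor, aromatase, 2 further steroidogenic proteins and anti-Müllerian hormone. CYP11A1, the cholesterol side-chain cleavage enzyme, was the nearest gene of 7 control regions, none at its promoter. NR5A1, a regulator of steroidogenic genes, was the nearest gene of 2, also outside its promoter. INHA, the inhibin alpha subunit, had 1 control region on its gene body (fold 5.48) that the authors' annotation credits to a neighboring gene. None of these 3 genes had a testosterone region.

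Control-only promoters with the largest control fold included those of CCT5 (22.7), ITPRIP (21.4), TXN2 (20.96), ZNF570 (19.98), TMEM8B (19.3), ABL1 (19.2), TNPO1, a nuclear import receptor (18.9), STAMBP, a deubiquitinase (18.8), and CDC42SE2 (18.7). The CCT5 region (chromosome 5, 10249093 to 10250100) also lies within 1 kb of an end of ATPSCKMT. Other named promoter regions have such a neighbor too, among them those of ITPRIP (CFAP58), THAP9 (SEC31A), FOXL2 (FOXL2NB) and KAT7 (FAM117A). Outside promoters, the largest control folds belonged to a pair of regions nearest PPIAL4F, at 29.2 (chromosome 1, 144546495 to 144546812) and 19.9, in a family of multiple near-identical copies. TP53INP2 followed with 14.8. A set of 29 genes had a promoter region after testosterone only, among them ADI1 and CNPY4, and 10 of the 29 had a control region elsewhere on the gene body or within 1 kb of it. The share of control genes also marked after testosterone was 3.56% when any region on the gene body or within 1 kb counted, 0.0818% at a -log10 q of at least 5, and 0 at 10 or more.

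Gene lists fixed before the data were examined were then compared at promoters. Of their 333 genes, 207 were marked in control cells and 5 after testosterone, and these 5 were also marked in control cells. Immediate early and AP-1 genes were marked at 24 of 25 promoters in control cells and at 3 after testosterone. The 3 were FOSL2 (control fold 8.68) and FOSB (6.999), which encode AP-1 subunits, and IER2 (5.63), named after its values were seen. Inside the testosterone list IER2 had the largest fold of all (7.89, chromosome 19, 13152608 to 13152913). EGR1 (12.4) and JUN (9.90) were marked in control cells only. Among 10000 random lists of as many control-marked genes, matched on control fold, 1.58% kept 3 or more. With a promoter window of 500 bp the list kept 2 genes, and 5.9% of random lists kept as many. With one of 3 kb it kept 4, and 0.49% did. The share was 0.7% at a fold of at least 4, 1.13% for random lists that were not matched and 2.1% at a -log10 q of at least 5, where 1 gene, IER2, was kept. It was 2.84% when random lists were matched on the summed width of control regions instead, and 2.71% when they were matched on control pileup, choices made after seeing the data.

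Androgen-responsive genes were marked at 13 of 25 promoters in control cells, including ELL2 (10.8) and ERRFI1 (9.12), and at 1 after testosterone, KLF9, a Krüppel-like factor gene (control fold 3.95). In random lists, 21.7% kept as many. Writers, erasers and readers of histone acetylation were marked at 28 of 32 in control cells, with KAT7 (14.8) and KAT6A (13.0) the highest of those found there alone. BRD2, a bromodomain reader, was the 1 kept after testosterone (control fold 10.3), and 43.5% of random lists kept as many.

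No promoter of the other 9 lists was marked after testosterone within 1 kb of the gene start. With a window of 3 kb, 10 genes in place of 5 were marked in both conditions over all lists, and the number of lists with such a gene rose from 3 to 5. The 5 added genes, named after their values were seen, were CDKN1B of the cell cycle list, RPLP1 and EEF2 of the ribosomal list, HDAC5 and FOSL1. Granulosa identity and steroidogenesis genes had 9 of 30 promoters marked in control cells, with FOXL2 and FDX1, the ferredoxin that feeds steroidogenic enzymes (6.19), the highest. Ovulation and cumulus expansion genes had 7 of 20, including CEBPB (13.2) and RUNX1 (8.55), transcription factors induced by luteinizing hormone. Cell cycle genes had 18 of 30, including the ribonucleotide reductase gene RRM2 (9.45) and the kinase inhibitor gene CDKN1B (8.46). TGF-beta and BMP pathway genes had 17 of 30, including ID1 (11.98) and the receptor gene BMPR1A (10.3). Endoplasmic reticulum stress and apoptosis genes had 24 of 30, including CHAC1 (13.999) and ASNS (13.1), targets of ATF4. Glycolysis and mitochondrial energy genes had 23 of 30, including PFKP (9.57) and LDHB (7.52). Cholesterol and lipid synthesis genes had 21 of 25, including MVD (11.6), an enzyme of the mevalonate pathway. Ribosomal protein and translation genes had 22 of 30, including RPL10A (9.39) and RPL13 (8.09). Markers of other ovarian and blood cells had 1 of 26, the oocyte factor GDF9 (4.51), whose region also lies within 1 kb of an end of UQCRQ. Keeping none was frequent among random lists of these sizes: in each of the 12 lists, at least 56.5% of random lists kept none. A lower share kept in any 1 list was therefore not detectable.

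**Figure D4:**
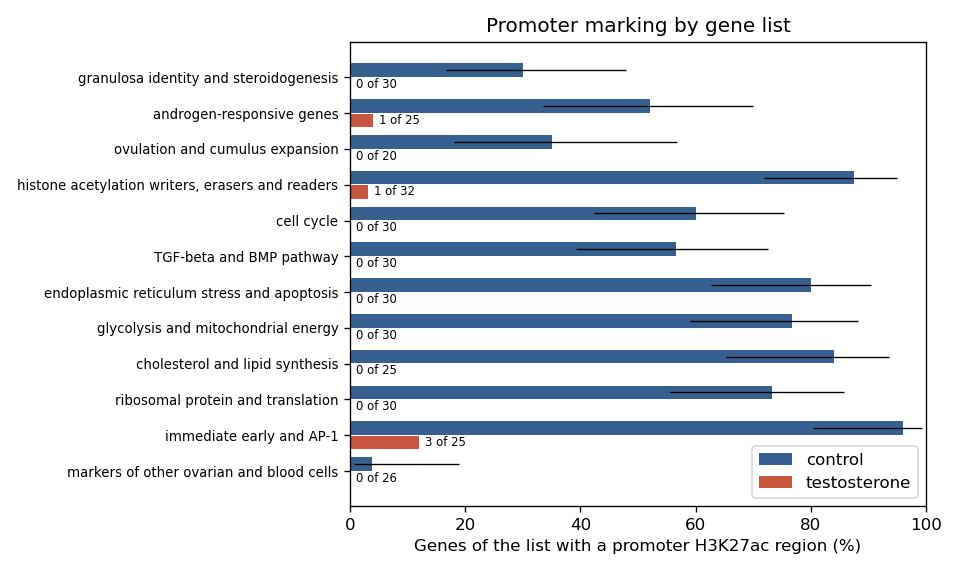
Share of each list's genes with a promoter H3K27ac region (horizontal axis, percent) in the control and the testosterone list, for 12 gene lists (vertical axis). Lines on the control bars are Wilson 95% intervals, the counts after testosterone are written beside the bars, and 9 lists have none.

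The last comparison asked, inside the control list, whether stronger regions were more often found again after testosterone. Control regions that overlapped a testosterone region had a median fold of 5.64 (interquartile range 4.51 to 7.82), and the rest one of 4.99 (4.08 to 6.31). The area under the ROC curve of control fold for being shared was 0.605 (0.560 to 0.651). Shared control regions were also wider, with a median of 638 bp against 410 bp, and the ROC area of width was 0.670. Among regions of like width (10 groups of equal size), a comparison added after seeing the data, the ROC area of fold was 0.542. Of the tenth of control regions with the highest fold, which held THAP9, MEIG1 and STT3B, 2.04% (1.50 to 2.78) were shared, against 0.628% (0.360 to 1.09) of the tenth with the lowest. Among the 604 control regions with the highest fold, 17 were shared (2.81%, 1.76 to 4.46). Ranked by pileup, 25 of 604 were (4.14%, 2.82 to 6.04), and the ROC area was 0.699. Inside the testosterone list the ROC area of fold for overlapping a control region was 0.558 (0.507 to 0.610).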

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

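The main tests were set before the data were examined, while sharing within 10 kb, gene bodies, random lists matched on width or pileup, strength at like width and the choice of the AP-1 list for comparison came after. Of 123 values under alternatives, 72 kept to the main value within its limits, 47 moved, 4 lost their side of the 2.5% limit and none reversed. The 72 include every value without merging and with every sequence name. Those values could not differ, since no regions of a list overlapped and all lay on the chromosomes used. The limits were wide for gene counts: 144 and 264 testosterone promoter genes still counted as kept to the main 186. At a -log10 q of at least 5 the ratio of region numbers was 1035, the shared share of testosterone regions 50%, their promoter share 60% and the share of control promoter genes kept 0.0818%. At 10 or more these were 3775, 100%, 0% and 0%, the ROC area was 0 and 100% of random lists kept as many as the AP-1 list, since 1 testosterone region remained. An equal -log10 q is not an equal -log10 p in the 2 lists, and at a -log10 p of at least 8 the ratio was 77.3. The shared share was 24.0% at a fold of at least 4, 23.3% with 50% overlap of the shorter region, 8.11% with reciprocal overlap, 47.4% within 1 kb, 78.1% within 10 kb and 2.81% against the reduced control list. A promoter window of 500 bp gave a promoter share of 24.0%, 1.52% of genes kept and 5.9% of random lists keeping as many AP-1 genes, and one of 3 kb gave 46.2%, 2.68% and 0.49%. Gene bodies gave 3.56% kept. The ROC area was 0.558 with reciprocal overlap, 0.542 at like width, 0.663 by -log10 p and 0.699 by pileup. Random lists matched on width gave 2.84%, and on pileup 2.71%. Apart from the thresholds, windows and sharing rules, whose construction sets the number of regions counted, the cause was not tested. No paired analysis was possible because each condition had 1 IP library, and for the same reason none could be left out.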

Other observations

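A few genes were the nearest gene of many control regions, over stretches of unlike length. NTMT1 was the nearest gene of 48 control regions (chromosome 9, over 215 kb), of which the strongest had a fold of 13.8, and of 1 testosterone region. ZFHX3, a transcription factor gene, was nearest to 47 control regions (over 1371 kb) and 12 testosterone regions, and GSE1 to 37 (506 kb) and 0. BCOR, a corepressor gene, was nearest to 30 (579 kb) and 0, and TBX2 to 26 (176 kb) and 3. The HOXB cluster (chromosome 17, 48528526 to 48728750) held 49 control regions covering 31.4 kb and 1 testosterone region, and the HOXC cluster held 30 and 2. The HOXA and HOXD clusters held 2 and 3 control regions and no testosterone region.

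Gene families defined by symbol differed in promoter marking in control cells. Proteasome subunit genes were marked in 29 of 40 cases (72.5%, 57.2 to 83.9), mitochondrial ribosomal protein genes in 43 of 77 (55.8%, 44.7 to 66.4) and zinc finger (ZNF) genes in 269 of 517 (52.0%, 47.7 to 56.3). Potassium channel genes were marked in 17 of 96 cases (17.7%, 11.4 to 26.5), keratin genes in 2 of 55 and olfactory receptor genes in 0 of 392. After testosterone the counts were 1, 5, 5, 0, 0 and 0. Besides ZFHX3, the testosterone list had most regions nearest PDE4D (9, with 8 in introns and 0 shared), RBMS3 (6, with 0 shared) and GPR89A (5). The median local background of the regions at ZFHX3, PDE4D, RBMS3 and GPR89A was 2.24, 1.74, 1.72 and 1.99 times the lowest of the list.

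The paragraphs below weigh 3 patterns. For the first, bounds were set before the data were examined (for depth, on tag counts, in place of which the caller's backgrounds were used), apart from the test of power for the gene lists. That test and the tests weighed for the other 2 were chosen after the results were seen, while the 1.58% from which the third pattern arose was planned. The first pattern is the 31.6-fold difference in region number. The IP depth ratio of 1.031 argues against a shallower testosterone IP, while the input depth ratio of 1.892 lay between the bounds set for and against it, and caller settings could not be compared. Weaker enrichment over the whole testosterone IP was to give a ROC area of at least 0.8 and its absence one of at most 0.6. The area of 0.605 (0.560 to 0.651) left it open, as did 0.663 by -log10 p and 0.699 by pileup. At like width, tested afterwards, the area of fold was 0.542, while that of width itself was 0.670. The bound set for unrelated regions in the testosterone list (under 50% overlap) was met at 28.1%, but such regions add to that list and cannot make it shorter. Loss at certain gene lists could not be judged: 1 of the 12 lists lay outside the random lists, which met the bound against it (at most 1), but that bound was wrong, as keeping none would have been rare in 0 of the 12, and an effect of testosterone cannot be told apart from a difference between single IP libraries.

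A second pattern is that most testosterone regions lay outside control regions. Random placement of all of them, evenly along each chromosome, is argued against by the 69.585% within 10 kb of a control region (shuffles at most 14.98%) and, for the 132 farther away, by the 10.606% (6.42 to 17.0) within 1 kb of an end of a coding gene (at most 6.06%), although part of them may still be random. The shuffles drew every position with equal weight, so false positive regions that favor certain places were not covered. The median local background of these testosterone-only regions was 1.103 times the lowest, under the bound of 1.5 set against high input background. The caller admits a region only where its pileup stands well above the local background. At their median pileup of 10, a median background of 2 times the lowest could hardly have passed. This value therefore cannot decide on high input background. The same acetylated stretches, called beside the control segment, may account for a part: 43.318% lay within 2 kb of a control region, between the bounds of 20% and 75%. A redistribution of the mark by testosterone was not tested separately and stays open.

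The third pattern is that the immediate early and AP-1 list kept 3 promoters. It was singled out because 1.58% of random lists matched on control fold kept as many. Of lists matched on control pileup 2.71% did, and of those matched on width 2.84%, just past the bound of 2.5%. Most matched lists still kept fewer, so stronger control promoters or wider control regions may account for a part of it at most. Chance among the 12 lists was not excluded, as 7.32% of 10000 families of 12 random lists held a list as far out. That is past the bound of 5%, though most families held none. No biological explanation was tested.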
